A study of Mus musculus with 2 samples.

How the data were processed

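RNA was measured in single cells of mouse placenta at embryonic day 9.5 with 10x Genomics Chromium 3′ chemistry, in 2 libraries, 1 from pooled placentas labelled WT (control) and 1 from pooled placentas labelled GATA DKO. Per the labels, dams with floxed Gata2 and Gata3 were mated with males carrying floxed alleles of both genes and a Gcm1 Cre driver. The file names of the library labelled GATA DKO point to a Gcm1 knockout instead, and the label was followed. The deposited files hold counts of UMIs per gene and barcode, which the authors made with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes and the file headers. The annotation release is not given in the sources used here. Each library's filtered list of cell barcodes was used, in which every barcode had at least 500 UMIs, and for the GATA DKO library also the unfiltered counts (1243447 barcodes with a UMI, 54261452 UMIs). The control's unfiltered barcode and gene lists were not used here. All columns belonged to a sample (0 without one).

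Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, which 14405 control and 5846 DKO-labelled barcodes met. Doublets were scored per library with Scrublet (scanpy 1.11.5, anndata 0.12.19), and the highest-scoring 0.8% per 1000 cells were left out, 1660 (11.5%) and 273 (4.67%). Scrublet's automatic threshold would have left out 1016 and 73. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together on 3000 variable genes, 40 principal components and 15 exact neighbours with the Leiden method (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) at resolution 1 and seed 0. Gata2, Gata3, Gcm1, Xist, Y-linked, mitochondrial and hemoglobin genes were left out of the clustering. No batch correction was applied, since library and group coincide.

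Clusters were named from 22 marker sets. A marker counted as raised with at least 10 UMIs and a 2-fold higher level than in the other cells, with 10 CPM added to both. Of the sets with at least 3 raised markers, the one with the highest mean log2 fold gave the name, with "-like" added. A name was dropped when another set had more markers among the 10 leading genes, or when none of its own were among them and under 66.7% were raised. This last condition was set after the clusters had been seen. It alone left without a name cluster 31 (otherwise monocyte or dendritic cell-like) and trophoblast sub-clusters 2 (junctional zone), 4 and 14 (giant cell), 9 (syncytiotrophoblast layer II), 10 (labyrinth progenitor) and 12 (layer I). Trophoblast-like cells were clustered again on their own with the same settings.

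Shares have exact binomial (Clopper-Pearson) 95% intervals. Within each class of at least 100 cells per library, UMIs were summed and given as CPM with exact Poisson 95% intervals, and log2 ratios (GATA DKO over control) with exact conditional intervals. A count of 0 was set at a floor of 3 counts over the class, and the fold was then given as a bound. With 1 library per group, no p-value and no number of changed genes was computed. The median log2 ratio of 28 gene lists was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes the 2 libraries and is not a test between genotypes. Each list median also had a 95% interval from resampling the list's members with replacement. List members needed 20 UMIs over both libraries, and a list needed 5 members, or 3 if it had under 8 genes.

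Genes were named by rule: at least 50 UMIs and 50 CPM in the higher library, a 2-fold difference, Poisson intervals that do not overlap, and no other class of that library above 10 times their level. Mitochondrial, ribosomal protein, hemoglobin, sex-linked and predicted genes were left out. The 10 largest ratios in each direction were named in trophoblast-like cells and 5 in the other classes, with Gata2, Gata3 and Gcm1 always named and the 2 highest and 2 lowest members of each list allowed. The lists were those of syncytiotrophoblast layers I and II, labyrinth progenitors, junctional zone, giant cells, cathepsins, trophoblast transcription factors, transporters, cholesterol and steroid synthesis, glycolysis, hypoxia, S phase, G2 and M phase, p53, stress, immediate early, interferon, vascular, niche ligand, embryonic and adult-type globin, heme, imprinted, matrix, junction, Wnt, Fgf and Notch, and sex-linked genes. Gene positions were taken from GENCODE annotation on GRCm38.

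Alternatives, 1 at a time, were no doublet removal, the automatic doublet threshold, 2000 UMIs, 10% mitochondrial UMIs, all deposited barcodes, resolutions 0.5 and 2, 1500 variable genes, and each library clustered alone. Others were trimmed mean scaling (edgeR 4.0.16), CPM without mitochondrial, ribosomal protein and hemoglobin genes, equal weight of cells, thinning to 1000 UMIs per cell, subtraction of free RNA by each library's all-barcode profile and embryonic globins, no minimum for list members, and 20 UMIs for named genes. The marker sets, lists, rules and these alternatives were fixed before the data were examined. Added afterwards were a minimum of 0.5% mitochondrial UMIs, shares without erythroid cells, cluster names without the condition set later, leaving out barcodes in both lists, visceral endoderm-like cells of cluster 8 alone, lists without members that another class holds above 10 times their level, and a further subtraction of free RNA. The last took the control's all-barcode profile with embryonic globins, and for the GATA DKO library the barcodes of 1 to 9 UMIs with adult β-globins.

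The computation of ratios and list percentiles was tested on simulated trophoblast sums of 16557 genes. Intervals held the set ratio in 92%, 94%, 96% and 100% of 50 genes at folds of 2, 4, 0.5 and 0.25. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.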

Results

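Single cells of mouse placenta at embryonic day 9.5 were profiled by droplet RNA sequencing in 2 libraries, 1 labelled WT, called control here, and 1 labelled GATA DKO. Per the labels, dams carried floxed alleles of both Gata2 and Gata3, the sires brought a Cre recombinase driven by Gcm1, and placentas of each kind were pooled. The number of placentas in each pool is not given in the sources used here. The names of the second library's files point to a knockout of Gcm1 where its label gives GATA DKO, and which of these holds stays open. The deposited cell lists held 20908 barcodes with 125972276 unique molecular identifiers (UMIs) in the control and 11611 barcodes with 39997880 UMIs in the library labelled GATA DKO. After filtering and doublet removal, 12745 control cells (median 2064 UMIs and 935 genes) and 5573 cells of the DKO-labelled library (median 4829 UMIs and 1797 genes) were kept. With 1 library per group there were no replicates, so no difference could be set against a spread between placentas. Every interval printed below is a 95% interval for counting error only, unless it is said to come from resampling of list members.

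The first question was whether the targeted genes were lower in the library labelled GATA DKO. Over all trophoblast-like cells they were not, while in the 1 trophoblast sub-cluster with Gcm1 UMIs the counts left the direction open. In trophoblast-like cells, Gata2 stood at 126 counts per 1000000 UMIs of the class (CPM; 121 to 132, from 2231 UMIs) in the control and at 317 CPM (297 to 338, from 941 UMIs) in the DKO-labelled library, a log2 ratio of 1.33 (1.22 to 1.44). Gata3 stood at 48.4 CPM (45.2 to 51.8, 856 UMIs) and 66.4 CPM (57.4 to 76.3, 197 UMIs), a log2 ratio of 0.46 (0.22 to 0.68). Both genes encode zinc finger transcription factors of trophoblast. A Gata2 UMI was found in 47.0% of the 1558 control trophoblast-like cells (44.5 to 49.5%) and in 49.6% of the 676 in the DKO-labelled library (45.7 to 53.4%), at median depths of 4717.5 and 2458 UMIs. With every cell thinned to 1000 UMIs these shares were 11.6% and 25.1%. For Gata3 the shares were 28.7% and 19.2%, and 4.49% and 5.47% after thinning. Visceral endoderm-like cells, taken as background at median depths of 2266 and 1587 UMIs, had a Gata2 UMI in 2.34% and 4.33% of cells and a Gata3 UMI in 0.501% of 599 and in 6 of 300 cells. Thinned, the visceral endoderm-like shares were 0.668% and 2.67% for Gata2 and 0.334% and 0.667% for Gata3. Decidual stroma-like cells held both genes too, with Gata2 at 64.1 and 103 CPM and Gata3 at 21.4 and 175 CPM.

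Gcm1, which drives the Cre and marks the syncytiotrophoblast precursors of the labyrinth, was close to undetectable. It gave 8 UMIs in 5 trophoblast-like cells of the control and 2 UMIs in 1 cell of the DKO-labelled library, all of these in trophoblast sub-cluster 10. Elsewhere the control had 2 Gcm1 UMIs in visceral endoderm-like cells, at 0.530 CPM against 0.453 CPM in trophoblast-like cells, and 1 each in cluster 0 and megakaryocyte-like cells. The DKO-labelled library had 1 in endothelium-like cells. In that sub-cluster, of 69 and 27 cells, Gata2 was at 223 CPM (197 to 252, 261 UMIs) and 154 CPM (82.1 to 264, 13 UMIs), a log2 ratio of −0.53 whose interval included 0 (−1.46 to 0.27). A Gata2 UMI was in 69.6% and 29.6% of its cells, at median depths of 9444 and 2163 UMIs. Gata3 there had 10 and 3 UMIs, a log2 ratio of 2.06 (−0.44 to 4.01). Gata2 (ENSMUSG00000015053) lies on chromosome 6 from 88193891 to 88207032 on the plus strand of GRCm38, and Gata3 (ENSMUSG00000015619) on chromosome 2 from 9857078 to 9890034 on the minus strand. Gcm1 (ENSMUSG00000023333) lies on chromosome 9 from 78051924 to 78065624 on the plus strand. The libraries count the 3′ ends of transcripts, and the labels do not say which exons are removed, so these counts may not show the deletion at all. The class-wide sums also follow cluster makeup. Cluster 17, with Gata2 at 539 CPM, gave 38.4% of the class's UMIs in the DKO-labelled library and 0.369% in the control. Cluster 16, with Gata2 at 98.2 CPM, gave 8.87% and 48.5%. Gcm1 drives the Cre, and a lack of Gcm1 UMIs does not show which cells had expressed it. The class-wide sums could therefore not decide whether the targets were deleted. The counts of sub-cluster 10 are too few to decide, so the group name is used only as a label of the library. Every direction below is between these libraries and not between verified genotypes.

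The cell makeup differed in most classes between the libraries, while the share of trophoblast-like cells was close to equal at the minimum of 1000 UMIs and unequal at 2000. They were 12.2% of control cells (11.7 to 12.8%) and 12.1% of the DKO-labelled library (11.3 to 13.0%), or 14.4% and 12.1% with erythroid cells left out of the total. With a minimum of 2000 UMIs they were 17.4% and 9.18%, and with at least 0.5% mitochondrial UMIs 8.98% and 6.45%. Primitive erythroid-like cells, the nucleated red cells of the early embryo, were 14.9% of the control (14.2 to 15.5%, 1893 cells) and 0.0359% of the DKO-labelled library (0.00435 to 0.130%, 2 cells). The control share was 27.3% with a minimum of 2000 UMIs. The DKO-labelled share was 31.9% with all deposited barcodes and 4.14% with each library clustered alone, although only 1 barcode of its list had over 5% embryonic globin and 4429 had over 5% adult β-globin. Hematopoietic progenitor-like cells were 4.01% (511 cells) and 0.287% (16 cells), and megakaryocyte-like cells 1.61% and 0 of 5573 cells, which allows a share of up to 0.0662%. Visceral endoderm-like cells, a tissue of the yolk sac, had shares of 4.70% (4.34 to 5.08%) and 5.38% (4.81 to 6.01%). Parietal endoderm-like cells were 0.855% of the control and were not found in the DKO-labelled library.

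Classes named for blood, stroma and vessels also split by library. B cell-like cells (10.2%) and neutrophil-like cells (4.10%) were found in the control alone, and T cell-like cells were 4.64% and 0.0359%. Cluster 0, led by Ebf1, H2-Aa and Cd79a with all 4 B cell markers raised, held 18.8% of the control and no cell of the DKO-labelled library. It was left unnamed and is not part of the B cell-like share. Decidual stroma-like cells were 1.12% of the control (143 cells) and 27.6% of the DKO-labelled library (1538 cells). Cluster 3, led by Rarres2, Ctsk and Aoc1 with all 8 decidual stroma markers raised, held 0.0235% and 23.2%. Mesenchyme-like cells were 0.0863% and 5.08%, pericyte-like cells 0.0235% and 2.12%, natural killer-like cells 8.24% and 3.79%, and endothelium-like cells 6.07% and 8.45%. A cluster that sits almost wholly in 1 library may stand for that library rather than for a cell type. Among the other unnamed clusters, cluster 5 (Lyz2, Ms4a6c) held 5.75% and 4.09%, cluster 19 (Scgb1a1, Hbb-bt) 0.0471% and 4.83%, cluster 21 (Tagln, Acta2) 0.722% and 2.94%, cluster 26 (Crabp2, Sox11) 0.942% and 0.0359%, and cluster 31 (Igha, Jchain) 0.730% and 0.0179%. Cluster 21 had 7 of the 9 mesenchyme markers raised, against 5 of 9 in the named mesenchyme-like cluster, and is not part of the mesenchyme-like share. Uterine epithelium-like cells were 0.165% of the control and 0 of the 5573.

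**Figure D1:**
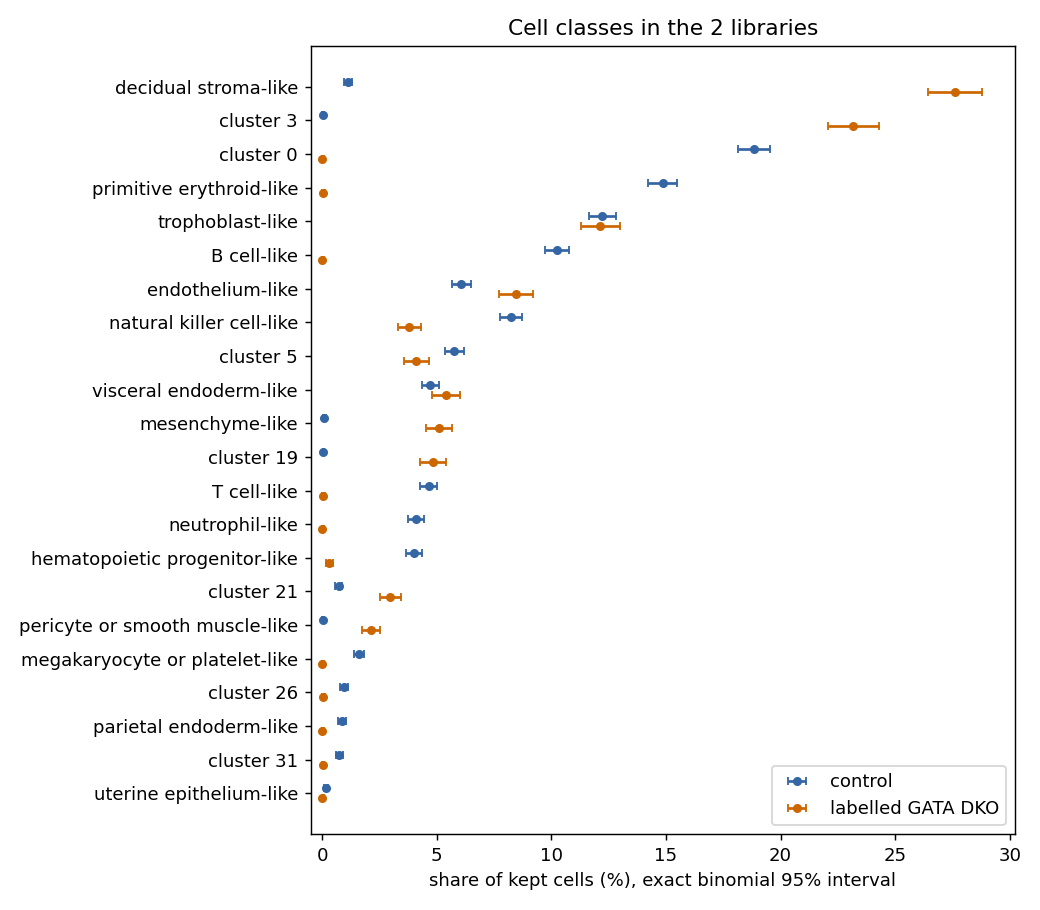
Share of kept cells (percent) in each cell class of the control and of the library labelled GATA DKO, with exact binomial 95% intervals for counting error. Trophoblast-like cells take 12.2% and 12.1%, while primitive erythroid-like cells take 14.9% and 0.0359% and decidual stroma-like cells 1.12% and 27.6%.

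Within trophoblast, most sub-clusters were filled mainly by 1 library. Trophoblast giant cell-like cells, which line the implantation site and secrete prolactin-family hormones, made up 24.2% of control trophoblast-like cells (22.1 to 26.4%, 377 cells) and 3.25% in the DKO-labelled library (2.05 to 4.89%, 22 cells). The summed level of the giant cell list went the other way, at 10615 and 22617 CPM. Junctional zone-like cells, the endocrine spongiotrophoblast and glycogen lineage, made up 5.97% (4.84 to 7.26%) and 2.66% (1.59 to 4.18%). The direction of the giant cell-like share changed with the doublet setting, under which the cells were also clustered and named anew. The share was 28.0% and 30.0% with the automatic threshold and 24.99% and 39.7% without doublet removal. Whether the doublets or the naming changed it was not tested. Part of the naming rule was set after the clusters had been seen. Without it giant cell-like shares were 36.3% and 7.84%, junctional zone-like shares 19.96% and 3.70%, and sub-cluster 10 was labyrinth progenitor-like. Most DKO-labelled trophoblast-like cells fell into 2 unnamed sub-clusters with almost no control cells. Sub-cluster 1, led by hemoglobin genes and Cartpt, held 44.7% against 0.257%, and sub-cluster 3, led by Prl8a9 and Ptgr1, held 26.9% against 0.128%. The giant cell set was the closest to sub-cluster 3, with 4 of its 12 markers raised (Prl2c5, Prl4a1, Ctsj and Hand1), but the name was dropped because none of its markers was among the 10 leading genes and Prl8a9 of the junctional zone set was. Sub-cluster 9, led by Thbd and Serpine1 and with 3 of the 6 markers of syncytiotrophoblast layer II raised, held 2.82% of the control and 7.99% of the DKO-labelled library. Gata2 was at 324 CPM (278 to 376) and 617 CPM (550 to 689) in this sub-cluster. No sub-cluster met the full rule for either syncytiotrophoblast layer, the fused cells that exchange nutrients and gas in the labyrinth. Without the later part of the rule, sub-cluster 12 was layer I-like (5.33% and 0.444%) and sub-cluster 9 layer II-like. The fusion gene Syna gave 13 and 0 UMIs in trophoblast-like cells and Synb 1 and 2. Outside them, Synb had 5 UMIs in primitive erythroid-like cells and 1 in cluster 0 of the control, and Syna 1 in cluster 5 of the DKO-labelled library.

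Gene expression was then compared within trophoblast-like cells as a whole, a class held mostly by clusters 10, 14, 15 and 16 in the control and by clusters 17 and 20 in the DKO-labelled library. Prolactin-family genes of the placenta went both ways. Prl7b1 (ENSMUSG00000021347) was at 506 CPM (495 to 516) in the control and 1.01 CPM (0.209 to 2.95) in the DKO-labelled library, a log2 ratio of −8.97, and Prl8a9 (ENSMUSG00000006490) was at 32.6 CPM (30.0 to 35.4) and 543 CPM (517 to 570), a log2 ratio of 4.06. Cartpt, a neuropeptide precursor gene, had no UMI in the control and 126 CPM in the DKO-labelled library, where 5.62% of cells held one, so it was at least 741-fold higher against a floor of 3 counts over the class. Thbd, which encodes the anticoagulant receptor thrombomodulin, was at 25.9 and 296 CPM, and Serpine1, an inhibitor of plasminogen activators, at 28.1 and 283 CPM. Lower in the DKO-labelled library were Fgfbp1, a carrier of fibroblast growth factors (247 and 3.37 CPM, log2 −6.19), the placental cathepsin Cts7 (228 and 7.41 CPM, log2 −4.94) and the lipoprotein lipase gene Lpl (57.8 and 5.06 CPM, log2 −3.52).

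The remaining genes that met the naming rule had log2 ratios between 3.41 and 4.73 when higher and between −4.64 and −2.89 when lower. Higher were Tppp3 (4.73), Emp3 (3.64), Igfbp4 (3.55), which encodes a binding protein of insulin-like growth factors, the adrenergic receptor gene Adra2b (3.49), the calpain gene Capn2 (3.49) and Mustn1 (3.41). Lower were Tpm3-rs7 (−4.64), Lysmd2 (−4.01), Rgs5 (−3.66), the linker histone gene Hist1h1b (−3.27), Wdfy1 (−3.14) and the transcription factor gene Batf3 (−2.89). Several of these genes lead clusters that 1 library fills for the most part: Cartpt, Thbd and Serpine1 lead cluster 17, Prl7b1 cluster 15, Fgfbp1 cluster 16 and Batf3 cluster 14. Their ratios cannot be separated from the cluster makeup of the libraries. Prl8a9 and Cts7 lead cluster 20, with 69 control and 196 DKO-labelled cells, and of these Cts7 was lower in the DKO-labelled library. Cts7 is also among the leading genes of sub-clusters 13 (72 control and 9 DKO-labelled cells) and 14 (21 and 26). Its ratio cannot be separated from the makeup either. Emp3, Igfbp4 and Mustn1 reached 706, 599 and 419 CPM in another class of the DKO-labelled library, against 76.8, 102 and 55.3 CPM in its trophoblast-like cells. All 20 genes were also named when the minimum was 20 summed UMIs in place of 50.

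Among the gene lists, those of mitosis and of the junctional zone lay below nearly all random lists. For G2 and M phase genes the median log2 ratio was −0.88, at percentile 0.01 of 10000 random lists matched on expression, with 14 of 16 members lower in the DKO-labelled library. The lowest were the kinetochore gene Cenpf (106.6 and 24.6 CPM, log2 −2.12) and the proliferation marker Mki67 (93.7 and 27.6 CPM, −1.76), and the highest were Cdk1 (0.38) and Ube2c (0.12). S phase genes had a median of −0.40 at percentile 16.2, with 12 of 16 lower, from Ung (−1.08) and Slbp (−0.79) to Mcm6 (0.21) and Pcna (1.83). The junctional zone list had a median of −0.90 at percentile 0.08, with 7 of 10 measured members lower. Beside Prl7b1, its lowest member was Ascl2, a transcription factor gene needed for spongiotrophoblast (175 and 37.1 CPM, log2 −2.24), and Prl8a9 and Prl7a2 (2.13) were its highest. The median of all genes in this class was −0.23, and −0.11 after scaling by trimmed mean factors. These 2 lists were picked out after all list medians were seen. Resampling of list members gave an interval of −1.12 to −0.52 for the G2 and M phase median. For the junctional zone median it was −1.64 to 0.75, which includes 0. Like the ratios of the named genes, the list medians of this class cannot be separated from its cluster makeup. Cluster 16 gave 48.5% of its UMIs in the control and 8.87% in the DKO-labelled library, and cluster 17 gave 0.369% and 38.4%. Under 0.5% of UMIs were mitochondrial in 43.4% and 55.8% of the cells. With each cell weighted equally the G2 and M phase median was −0.37, and with only barcodes of at least 0.5% mitochondrial UMIs the junctional zone median was 0.20.

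Giant cell and lineage genes were split. The trophoblast giant cell list had a median of −0.035 at percentile 69.6. Its highest members were Hand1, a transcription factor gene of giant cells (328 and 1321 CPM, log2 2.01), and Prl4a1 (1.76), and its lowest were Prl3d2 (−1.90) and Prl3d1 (−1.61), placental lactogen genes whose near-identical copies share reads. Of 16 trophoblast transcription factor genes, 8 were higher and 8 lower, with a median of −0.0023 at percentile 83.1, from Tfap2a (2.13) and Hand1 to Dlx3 (−2.09) and Ascl2. The labyrinth progenitor list had a median of −1.08 at percentile 3.44, with 4 of 5 members lower, among them Met (−2.23) and Cdh1 (−1.91), which encodes E-cadherin. For syncytiotrophoblast layer II only 3 genes could be measured, Slc16a3 (2.05), Igf1r (1.32) and Vegfa (1.19), with a median of 1.32 at percentile 98.5. Layer I had a median of −0.50 at percentile 32.9. Weighted by cell, the medians of the labyrinth progenitor and layer II lists were −0.69 and 0.86, and after thinning the progenitor median was −0.27.

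The hypoxia, p53, interferon and matrix lists had high medians, and most measured interferon and matrix genes were abundant in another class. The hypoxia response list had a median of 0.40 at percentile 99.3, with 10 of 14 members higher, led by Ddit4 (1.21) and Vegfa, and with Car9 (−1.75) and Ndrg1 (−0.80) lowest. The p53 target list had a median of 0.43 at percentile 98.9, with Trp53inp1 (1.09) and Mdm2 (0.76) highest and Perp (−0.81) and Phlda3 (−0.26) lowest. For the interferon response list the median was 1.66 at percentile 99.99, and for extracellular matrix 0.81 at percentile 99.99. Another class of the higher library held over 10 times the level of 7 of the 8 measured interferon genes and 10 of the 14 matrix genes. Free RNA was also subtracted by a method chosen after the data were seen. The medians of the hypoxia, interferon and matrix lists were then −0.16, −1.36 and −0.088. The barcodes of 1 to 9 UMIs used by this method held 0.369% embryonic globin, against 1.01 CPM in DKO-labelled trophoblast-like cells. These medians are thus uncertain. The subtraction planned beforehand gave −0.60 for interferon and −0.043 for matrix genes. Its share of 10.5% for the DKO-labelled library rested on 2541 embryonic globin UMIs, 85.4% of them in 2 barcodes, so it says little there. The vascular signalling list had a median of 0.87 at percentile 99.9, with Kdr (2.32) and Tie1 (2.03) highest and Flt1 (−1.87) and Ephb4 (−1.43) lowest. Without its 6 members that another class held over 10 times their level, the vascular median was −0.86. The dissociation and immediate early list had a median of −1.0 at percentile 0.06, and 0.93 without 11 such members of 14. Thinned to 1000 UMIs per cell, the p53 median was −0.018 and the immediate early median −0.35, and with equal weight of cells the p53 median was −0.093.

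The other lists lay within the middle 95% of random lists in trophoblast-like cells. Their medians were −0.47 for placental cathepsins, −0.11 for nutrient transporters, −0.25 for cholesterol synthesis, 0.10 for steroid hormone synthesis, 0.071 for glycolysis, −0.18 for the integrated stress and unfolded protein response, and 0.37 for hematopoietic niche ligands. They were −0.53 for heme synthesis and red cell maturation, −0.19 for imprinted genes, −0.41 for epithelial junctions and keratins, −0.50 for Wnt, Fgf and Notch ligands and targets, and 0.10 for sex-linked transcripts. Thinned, the cholesterol synthesis median was 0.20. Over the alternatives the glycolysis and niche ligand medians kept their sign, and each of the other medians above changed sign under some alternative. The heme synthesis median went from −1.04 to 1.04. The globin lists lay outside the middle 95%, with medians of −10.04 for embryonic and 6.61 for adult-type globins.

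**Figure D2:**
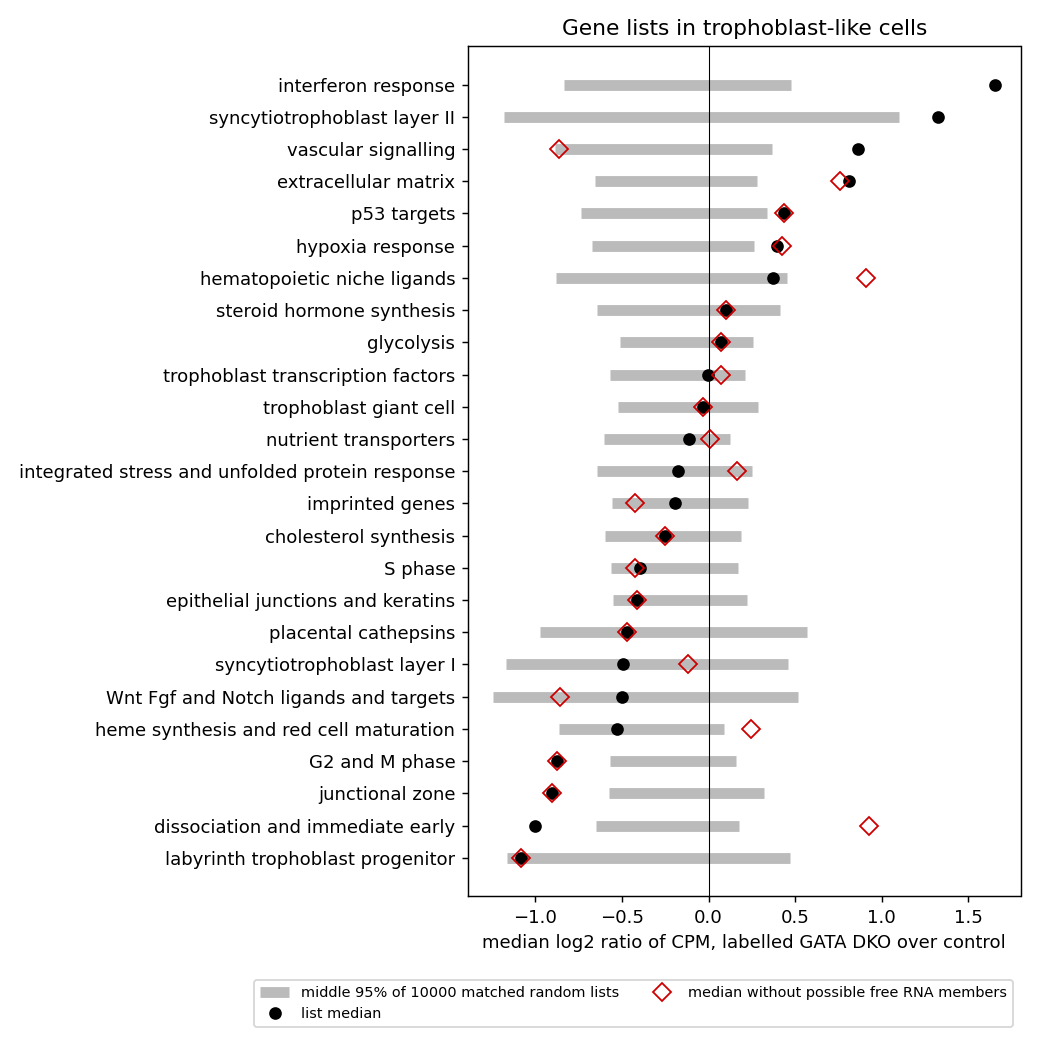
Median log2 ratio of CPM (library labelled GATA DKO over control) of each gene list in trophoblast-like cells, as black dots, with the middle 95% of 10000 matched random lists as grey bars. Red diamonds give the median without members that another class holds over 10 times their level. G2 and M phase (−0.88) and junctional zone genes (−0.90) lie below their grey bars and have no such members, while the immediate early list moves from −1.0 to 0.93.

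Most visceral endoderm-like cells of both libraries were in cluster 8, but the deeper cells of cluster 28 gave 57.1% of the class's UMIs in the control and 39.2% in the DKO-labelled library. In the class as a whole, the genes of cholesterol synthesis were higher together in the DKO-labelled library. The list's median was 1.36 at percentile 100 of the random lists, with 16 of 17 members higher. No member was held over 10 times higher by another class, but this bound cannot exclude free RNA at the share estimated below. Fdps, which makes farnesyl diphosphate, was at 39.8 CPM (33.7 to 46.7) in the control and 133 CPM (108 to 162) in the DKO-labelled library, and Hmgcs1, an early enzyme of the mevalonate pathway, was at 28.6 CPM (23.5 to 34.6) and 90.9 CPM (70.4 to 115). Idi1 and Ldlr, the receptor gene for low-density lipoprotein, both had a log2 ratio of 2.23, and Nsdhl was lowest at −0.0072. Another class of the DKO-labelled library held Fdps at 370 CPM and Hmgcs1 at 124 CPM. The sums rested on 300 DKO-labelled cells, and with every cell thinned to 1000 UMIs the median was 0.41. Over 18 alternatives, both subtractions of free RNA included, the median ranged from 0.41 to 1.60. Within cluster 8 alone, a comparison chosen after the data were seen, it was 0.85, with Fdps at 1.83 and Hmgcs1 at 1.25. The same list had a median of 1.46 in decidual stroma-like cells, with 15 of 17 members higher, and there 0.57 after thinning and 0.32 with all deposited barcodes. It was 0.40 in natural killer-like cells, 0.30 in cluster 5, −0.25 in trophoblast-like and −0.073 in endothelium-like cells. Rbm15 (log2 1.75), the kinase gene Sgk1 (3.15) and the heme synthesis gene Alas2 (5.19) were also higher by the naming rule, with Alas2 at 2.97 without doublet removal. By adult β-globin and the barcodes of 1 to 9 UMIs, free RNA was estimated at 43.6% of the UMIs of DKO-labelled visceral endoderm-like cells, against 1.49% in the control by embryonic globins. The estimate depends on the barcodes used, since those of 10 to 100, 101 to 300 and 301 to 499 UMIs gave values over 100% (200.9, 250.7 and 115.5%). Barcodes of 1 to 9 UMIs held 0.369% embryonic globin, which at a share of 43.6% would exceed the 35.3 CPM found in these cells. Whether the UMIs of a red cell gene such as Alas2 come from these cells is therefore open. After the added subtraction Alas2 was at 6.35. Sgk1 was at −2.30 after subtraction of free RNA by the added method. Tpm3-rs7 (−4.97), Wdfy1 (−3.07), the fructose bisphosphatase gene Fbp2 (−3.00), Fcgrt (−2.72), which encodes the neonatal Fc receptor, and Pga5 (−2.55) were lower. Trophoblast giant cell genes (median 2.63) and interferon genes (2.80) stood high in this class too, with 7 of 8 and 5 of 6 measured members held over 10 times higher by another class.

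Endothelium-like cells lay mainly in cluster 6 in the control and cluster 13 in the DKO-labelled library. Interferon response genes were higher in the DKO-labelled library, with a median of 3.13 at percentile 100 and 12 of 13 members higher. Ifit1 was at 2.63 and 116 CPM (log2 5.46, 4.21 to 7.10) and Usp18 at 1.05 and 43.1 CPM (5.35), and Rsad2 was lowest (−0.82). No member was held over 10 times higher by another class. Imprinted genes were lower, with a median of −1.72 at percentile 0 and 13 of 15 members lower, among them Rtl1 (43.7 and 1.21 CPM, −5.17) and the growth inhibitor gene Cdkn1c (4095 and 126 CPM, −5.02). Igf2r (0.69) and Plagl1 (0.028) were the exceptions. The imprinted genes Mest and Dlk1 lead cluster 6, so part of this difference is that between the clusters. H19 was at 2472 CPM in cluster 6 and 134 CPM in cluster 13, and Xist at 61.9 and 2320 CPM. The cells compared thus differ in more than the library label, and the ratios of this class, interferon genes included, cannot be separated from that. A fetal or maternal origin of the cells was not tested. All 16 G2 and M phase genes were lower, with a median of −1.03 and Aurka (−1.79) and Tpx2 (−1.78) lowest. Vascular signalling genes had a median of 0.87 at percentile 99.9, with Tie1 (2.62) and Notch4 (2.19) highest, and matrix genes one of 2.53. By the naming rule the growth factor gene Ptn (2.63 and 566 CPM, 7.75), Ccl21a (0 UMIs and 276 CPM, at least 175-fold), the enkephalin gene Penk (0.526 and 67.3 CPM), Gdpd3 (6.85) and Adamtsl1 (6.80) were higher. A Ccl21a UMI was found in 3.40% of the DKO-labelled cells. Chrdl1 (−5.99), Dcaf12l1 (−5.81), the adrenergic receptor gene Adrb1 (−5.62), Tpm3-rs7 (−5.15) and Cdkn1c were lower. Under 0.5% of UMIs were mitochondrial in 88.1% of control endothelium-like cells and 12.1% of the DKO-labelled ones, and without such barcodes the matrix median was 0.71.

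Natural killer-like cells lay mainly in cluster 7 in the control and cluster 22 in the DKO-labelled library. Cell cycle genes were higher in the DKO-labelled library: all 16 S phase genes (median 1.51) and all 16 G2 and M phase genes (median 1.72), both at percentile 100. Ccnb2 (log2 2.67) and Top2a (2.25), genes of cell division, led the G2 and M phase list. Pcna, the clamp of DNA replication, was at 7.26 CPM (5.39 to 9.57) and 55.9 CPM (47.3 to 65.5). Median depths were 3137.5 and 12881 UMIs, 61.0% and 15.6% of cells had under 0.5% mitochondrial UMIs, and with only barcodes of at least 0.5% mitochondrial UMIs the medians were 0.91 and 1.13. Olfr1369-ps1 (7.66), the purine nucleoside phosphorylase gene Pnp2 (7.55), the chemokine gene Ccl1 (5.32) and Rpgrip1 (4.94) were the other genes named as higher. The chemokine gene Ccl5 (867 and 7.82 CPM, −6.79), Cpa3 (−6.66), Cd3g (82.9 CPM and 0 UMIs, at least 74.2-fold lower), Tcrg-C4 (−5.80) and Klrb1b (−5.38) were lower. Ccl5 leads cluster 23, which had 222 control cells and none in the DKO-labelled library.

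Decidual stroma-like cells lay mainly in cluster 25 in the control, with 138 cells, and cluster 2 in the DKO-labelled library, with 1530 cells. Matrix genes (median 2.83) and all 16 G2 and M phase genes (median 2.76) were higher in the DKO-labelled library, and all 13 measured immediate early genes were lower (median −2.45). Col1a1, a fibrillar collagen gene, was at 15.3 and 580 CPM (log2 5.25, 4.37 to 6.31), Top2a at 6.11 and 106.5 CPM (4.12), and Fosb at 139 and 1.89 CPM (−6.20). The neuropeptide gene Tac2 (9.18), which leads cluster 2, Col6a1 (6.76), Susd2 (6.38), Prps2 (6.08) and the complement regulator gene Cfh (6.06) were named as higher. Rimklb (−10.84), Cts7 (−10.78), Pfpl (−10.44), Prl5a1 (−9.24) and Ceacam15 (−9.03) were lower. The control UMIs of Cts7, Pfpl, Prl5a1 and Ceacam15 came from 2.10, 2.80, 1.40 and 2.10% of its cells, and these genes are among the leading genes of trophoblast cluster 20 or sub-cluster 14, and Pfpl also of cluster 25. Cell quality differed with the library: 43.4% and 0.910% of these cells had under 0.5% mitochondrial UMIs, median depths were 2314 and 5615 UMIs, and the nuclear RNA Malat1 was at 100735 CPM in cluster 25 and 11740 CPM in cluster 2. With all barcodes of the deposited lists, the medians for matrix, G2 and M phase and immediate early genes were 0.14, 0.21 and −1.14. The all-gene median of this class was 0.33.

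Cluster 5, led by the myeloid genes Lyz2 and Ms4a6c, was the same cluster in both libraries. Its interferon response genes were higher in the DKO-labelled library in all 13 members, with a median of 1.02 at percentile 100 and a range of 1.02 to 1.24 over 10 alternatives. For this unnamed cluster the alternatives of doublet removal, UMI minimum, mitochondrial maximum, all barcodes and resolution were not run, so the range does not cover them. Usp18 (29.9 and 179 CPM, log2 2.58) and Isg15 (515 and 2021 CPM, 1.97) led, and Rsad2 (0.16) and Ifi27 (0.33) were lowest. The class II antigen presentation gene H2-Eb1 was at 32.1 CPM (24.5 to 41.4) and 5294 CPM (5064 to 5533), and the complement genes C1qb (5.82) and C1qc (5.26) and the interferon-inducible genes Ifi213 (7.29) and Ifi206 (7.16) were also higher. H2-Eb1 is among the leading genes of the cluster. In the control no other class of at least 100 cells, B cell-like cells included, held H2-Eb1 above 210 CPM. Ifi202b was at 344 CPM in the control with 0 UMIs in the DKO-labelled library, at least 42.9-fold lower, and Cd300e (−4.96), Trem1 (−4.84), Arhgef3 (−4.60) and the lymphotoxin gene Ltb (−4.42) were lower too. Immediate early genes had a median of −0.72 at percentile 0.13, with Jund (−1.58) and Jun (−1.26) lowest.

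Hemoglobin in cells that do not make it gave a measure of free RNA. Embryonic globins (Hbb-bh1, Hbb-y and Hba-x) were at 1902 CPM in control trophoblast-like cells and 1.01 CPM in those of the DKO-labelled library. The adult β-globins Hbb-bs and Hbb-bt, near-identical copies whose reads cannot be split with certainty, were at 194 and 16247 CPM. In visceral endoderm-like cells the values were 1832 and 35.3 CPM for embryonic and 18.8 and 36233 CPM for adult β-globins. Over 5% of UMIs were embryonic globin in 2397 barcodes of the control list and in 1 of the DKO-labelled list, and over 5% were adult β-globin in 93 and 4429 barcodes. In natural killer-like cells, prolactin-family RNA of trophoblast was at 154 and 65.9 CPM, against 13125 and 27604 CPM in trophoblast-like cells.

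Barcodes outside the deposited cell list were examined in the DKO-labelled library. Those with 10 to 100 UMIs, 31867 barcodes with 991793 UMIs, held 8.27% embryonic globin (8.22 to 8.33%) and 1.80% adult β-globin. At 1 to 9 UMIs the embryonic share was 0.369%, at 101 to 300 UMIs 0.0189% and at 301 to 499 UMIs 0.00781%, and the adult shares were 8.30%, 1.45% and 3.14%. These 3 bands were added after the first had been seen. Within 10 to 100 UMIs, barcodes that were also in the control's cell list held 14.7% embryonic globin (14.6 to 14.9%) and the others 7.08% (7.03 to 7.14%).

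**Figure D3:**
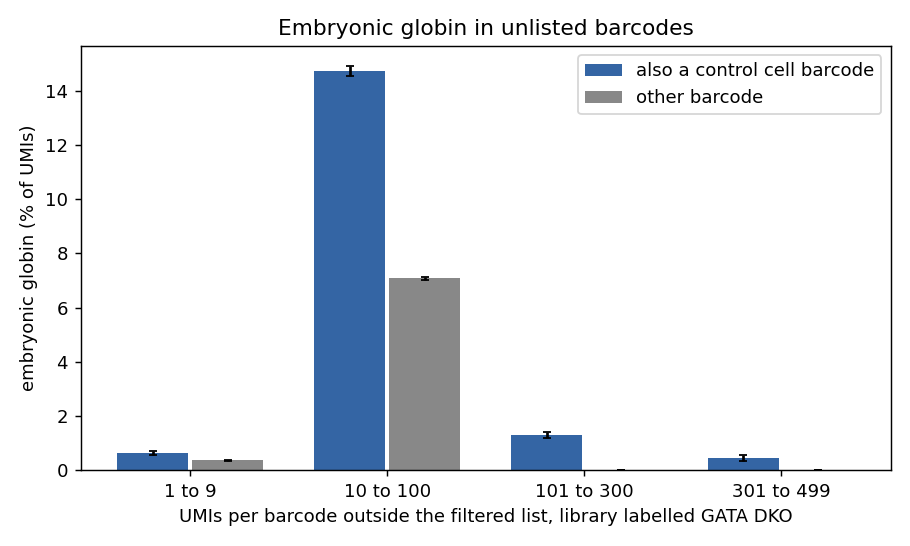
Embryonic globin as a percent of UMIs in barcodes outside the cell list of the library labelled GATA DKO, by UMIs per barcode, with exact binomial 95% intervals. Blue bars are barcodes that are also in the control's cell list and grey bars are others, with 14.7% and 7.08% at 10 to 100 UMIs.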

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

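The tests in this part were all chosen after the results they address had been seen. Barcodes outside the deposited cell list, used in no comparison of cell classes, held a signal: embryonic globins took 8.27% of UMIs in the barcodes of 10 to 100 UMIs of the library labelled GATA DKO, against 0.369% at 1 to 9 UMIs and 0.0189% at 101 to 300. In the same library 4112 barcodes with over 5% adult β-globin were not kept as cells, against 85 in the control.

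The embryonic globin in those barcodes sits beside a level of 1.01 CPM in trophoblast-like cells of the same library. Reads of the control library counted in the DKO-labelled one are a candidate source. At control barcodes with over 5% embryonic globin, 24.7% of the DKO-labelled library's UMIs (24.4 to 24.9%) were embryonic globin, against 0.299% at other control barcodes. Barcodes outside the control's list still held 7.08%, and their source stays open, as does any biological one, which was not tested. This band therefore gives no free RNA profile of the DKO-labelled library.

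Primitive erythroid-like cells were 14.9% of the control and 2 of 5573 cells in the DKO-labelled library. Less fetal tissue in the pool is argued against by the visceral endoderm-like cells, whose share ratio was 1.15 where the erythroid ratio was 0.00242. This speaks only against an even shortage of fetal tissue: parietal endoderm-like cells had 109 cells in the control and 0 in the DKO-labelled library, so uneven sampling of fetal tissues stays open. Red cells broken in the suspension are argued against by embryonic globin at 1.01 CPM in trophoblast-like cells, against 1902 CPM in the control. Loss of fetal blood before dissociation cannot be told apart from a difference of genotype, since hematopoietic progenitor-like cells were also fewer, at 0.287% against 4.01%, and 1 pool per group leaves handling and genotype, itself unchecked, confounded and open.

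Interferon genes were higher in trophoblast-like cells of the DKO-labelled library, with a median log2 ratio of 1.66. Free RNA of other cells may account for it: after the added subtraction, at a share of 19.6% of UMIs, the median was −1.36. That share depends on the barcodes used, since those of 10 to 100, 101 to 300 and 301 to 499 UMIs gave 90.1%, 112.4% and 51.8%. As 112.4% cannot be a share, the subtraction is uncertain. The barcodes of 1 to 9 UMIs that it used held 0.369% embryonic globin, while these cells held 1.01 CPM. At a share of 19.6% more would be found, so those barcodes give no clean profile of the free RNA in these cells. A difference of mouse strain or of library between the groups cannot be told apart from genotype, and strain is not given in the labels: the median was 3.13 in endothelium-like cells, which lie in cluster 6 in the control and 13 in the DKO-labelled library, and 1.37 in decidual stroma-like cells. In cluster 5 all 13 members were higher, with a median of 1.02. Its cells differed between the libraries too, with a C1qb UMI in 0.682% of control and 29.8% of DKO-labelled cells. The median in natural killer-like cells was −0.22, and 0.15 without 6 of 10 members that another class held over 10 times higher. A difference of cell makeup within these classes stays open and was not tested. A response to the genotype in cells outside trophoblast stays open and was not tested.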

How the results depend on the processing

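Alternatives with a minimum of 0.5% mitochondrial UMIs, without erythroid cells, without the naming condition set later, without barcodes in both lists, with cluster 8 alone for visceral endoderm-like cells, without list members that another class holds over 10 times their level, and the added subtraction were chosen after the data were seen; the others were planned. Of 2203 list medians under alternatives, 2033 stayed within their interval, 141 moved and 29 reversed; of 1020 gene ratios 894 stayed, 125 moved and 1 reversed; of 434 shares 308 stayed and 126 moved. Gata2 ranged from 1.31 to 1.58 and Gata3 from 0.29 to 0.71 over 15 alternatives. Over all trophoblast-like cells neither was thus lower in the DKO-labelled library under any of them. Such sums follow the cluster makeup of the class and could not decide whether the targets were deleted. No paired analysis was possible because each group has 1 library. Depth limits what can be said of Gcm1, Syna and Synb. For the values that follow the cause was not tested.

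Primitive erythroid-like shares of the control were 27.3% with 2000 UMIs, 10.8% with all barcodes and 19.1% with the mitochondrial minimum. In the DKO-labelled library they were 31.9% with all barcodes and 4.14% when clustered alone, where 1 barcode of that list has over 5% embryonic globin and 4429 have over 5% adult β-globin. Trophoblast-like shares were 17.4% and 9.18% with 2000 UMIs, 10.9% and 10.4% with all barcodes, 8.98% and 6.45% with the mitochondrial minimum, and 14.4% in the control without erythroid cells.

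Of trophoblast-like cells of the DKO-labelled library, 39.7% were giant cell-like without doublet removal, 30.0% with the automatic threshold and 24.3% with all barcodes, against 3.25% in the main analysis. These values were 9.76% at resolution 2, 5.06% with 1500 variable genes, 10.96% when clustered alone, 5.02% with the mitochondrial minimum and 7.84% without the later naming condition. In the control they were 28.0% with the automatic threshold, 28.0% with 10% mitochondrial UMIs, 28.4% at resolution 2, 27.9% when clustered alone, 18.5% with 2000 UMIs, 30.5% with all barcodes, 37.7% at resolution 0.5, 33.2% with 1500 variable genes, 29.6% with the mitochondrial minimum and 36.3% without the later condition. Junctional zone-like shares of the control were 18.6% without doublet removal, 16.4% with 2000 UMIs, 4.33% with 10% mitochondrial UMIs, 24.5% with all barcodes, 14.8% at resolution 0.5, 3.53% at resolution 2, 9.30% with the mitochondrial minimum and 19.96% without the later condition. In the DKO-labelled library they were 4.79% with 2000 UMIs and 5.02% with the mitochondrial minimum.

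In trophoblast-like cells the mitochondrial minimum gave log2 ratios of 1.58 for Gata2 and 0.71 for Gata3 and a junctional zone median of 0.20, reversed from −0.90. Trimmed mean scaling gave 1.45 for Gata2. G2 and M phase genes were at −0.37 with equal weight of cells and −0.47 thinned. Reversed were p53 targets (−0.093 equal weight, −0.018 thinned), immediate early genes (0.93) and vascular genes (−0.86) without members abundant elsewhere, and vascular genes with equal weight (−0.17). The added subtraction gave 1.54 for Gata2 and reversed hypoxia (−0.16), interferon (−1.36), vascular (−0.089) and matrix genes (−0.088). The planned one reversed interferon (−0.60), vascular (−0.059) and matrix genes (−0.043) and embryonic globins (2.68).

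Elsewhere the added subtraction reversed junction genes in cluster 5 (−1.15), adult-type globins in endothelium-like cells (−3.35), embryonic globins (1.35) and heme genes (0.14) in natural killer-like cells, and Sgk1 in visceral endoderm-like cells (−2.30). The planned one reversed adult-type globins in decidual stroma-like (−3.67) and natural killer-like cells (−5.77), and embryonic globins in endothelium-like (0.31) and visceral endoderm-like cells (3.78). Both subtractions set their share by globins, so the globin reversals in this part are not independent of the method. Without members abundant elsewhere, niche ligands in decidual stroma-like cells (1.27) and heme genes in natural killer-like cells (0.34) reversed. Heme genes there were also at 0.73 thinned and steroid genes at 0.037 with equal weight, and trophoblast transcription factors in visceral endoderm-like cells were at −0.073 with equal weight, −0.41 thinned and −0.34 in cluster 8 alone.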

Other observations

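The genes in this part were chosen after their values were seen, and no test was run on them. Wdfy1, which encodes an endosomal adaptor protein, was lower in the DKO-labelled library in all 6 classes compared, with log2 ratios of −3.14 in trophoblast-like, −4.00 in decidual stroma-like, −3.07 in visceral endoderm-like, −2.15 in natural killer-like, −1.43 in cluster 5 and −0.53 in endothelium-like cells. Tpm3-rs7, a tropomyosin-related sequence, was lower at −4.64 in trophoblast-like, −5.15 in endothelium-like and −4.97 in visceral endoderm-like cells, while in natural killer-like cells its interval included 0 (−0.64, −1.88 to 0.44). Ifi202b, an interferon-inducible gene, had 632 UMIs in control cells of cluster 5, 53 in natural killer-like and 22 in endothelium-like cells. It had 0 UMIs in the same classes of the DKO-labelled library. In decidual stroma-like cells it was lower too, at 12.2 CPM (8 UMIs) and 0.556 CPM (5 UMIs), log2 −4.46 (−6.41 to −2.66).

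Bst2, an interferon-inducible gene for a membrane tether of viruses, was higher in the DKO-labelled library in all 6 classes, from 0.72 in visceral endoderm-like to 3.24 in endothelium-like cells. Isg15 was higher in 5 of them, while in natural killer-like cells its interval included 0 (−0.41, −0.91 to 0.06).

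Between the libraries' barcode lists, 70 barcodes were shared where 35.7 were expected by chance. At the control's barcodes, the DKO-labelled library's unfiltered UMIs amounted to 0.211% of the control's UMIs, and the counts of both libraries were correlated across barcodes (Spearman's rho 0.739). Barcodes are not independent replicates.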
